A study of Homo sapiens with 6 samples.

How the data were processed

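RNA of HCT116 cells, an established human colorectal carcinoma line, was measured on 6 Affymetrix expression arrays. Per the labels, 2 arrays came from the wild-type parent, 2 from knock-in clone 1 and 2 from knock-in clone 2, and both clones are heterozygous for IDH1 R132H. Per the labels' protocols, 2000000 cells were plated, grown in McCoy's medium with 10% serum and harvested after 48 h, and the RNA was amplified from its 3' end before biotin labelling. The labels do not say whether the 2 arrays of a group are separate cultures, so p-values measure only the spread between these arrays.

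The deposited table holds 1 value per probe set and array on a log2 scale, between 2.76 and 14.38, and the values were used as deposited. Per the submitters' processing notes the software was Affymetrix Expression Console, with RMA and MAS5 named. The notes give no version and do not say which of the 2 methods made the table. The values are relative signals, so the number of arrays limits the precision and no depth applies.

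Each array holds 22277 probe sets. The 62 AFFX control probe sets were left out of the tests and used for array quality only, which left 22215. Of these, 19064 carried exactly 1 gene symbol (11963 genes), 1043 carried several and 2108 none. Genes were placed on chromosomes with the GRCh38.p14 annotation.

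Probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per cell population and 3 residual degrees of freedom. The comparisons were the mean of both clones against the parent, each clone against the parent, and clone 2 against clone 1, which tests the difference between the clones' changes. Benjamini-Hochberg adjustment ran over all 22215 probe sets, and a probe set passed at an adjusted p under 0.05. Because the clones have a coefficient each, the p-values describe arrays of these 3 populations and do not count the difference between clones as spread.

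The labels number the arrays 1 and 2 within each group without saying what the numbers stand for. The numbers were checked as possible pairs. Deviations from the group means correlated between groups across probe sets (Pearson r 0.546 for the parent and clone 1, 0.695 for the parent and clone 2, 0.559 for the 2 clones; Spearman 0.389, 0.521 and 0.401). Probe sets are not independent replicates. The cell population (2 degrees of freedom) held 49.2% of the sum of squares, the replicate number (1 degree) 37.3% and the remainder 13.5%. These shares are not scaled to degrees of freedom, so they do not show that the cell population outweighed the replicate number. A fit with the replicate number as a block (2 residual degrees of freedom) was therefore run beside the unblocked fit. Fold changes are identical in both fits.

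Both fits were tested on simulated data with 200 changed probe sets in each of 10 simulations. For both clones against the parent, the unblocked fit recovered 12.7% of changes of 0.5, 89.0% of changes of 1 and 98.8% of changes of 2 on the log2 scale, with 0% false calls. With the block the shares were 97.6%, 99.9% and 100%, and 7.81% of calls were false. The simulated data were drawn from the blocked fit, with its replicate-number effects and its spread. They favour that fit by construction and cannot show which fit suits the real arrays. For clone 1 alone the unblocked shares were 3.28%, 78.8% and 98.3%, and for clone 2 alone 2.54%, 80.4% and 98.6%.

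The report names genes by a rule set before the data were examined, as were the lists. The tests were too, apart from those said below to be chosen after the data or a result were seen. It uses probe sets with exactly 1 symbol, and for each gene the one with the highest mean signal. IDH1 and IDH2 are always named. For both clones against the parent the rule takes up to 12 genes per direction that pass and whose 4 knock-in arrays all lie on one side of both parent arrays. For the other comparisons it takes up to 6 per direction, and for each list up to 4 members with the smallest p. The same rule was applied to the blocked fit.

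All 33 gene lists had at least 8 measured members and were tested with camera in limma on 1 probe set per gene, with a preset correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry, with and without regard to direction, were run beside it. In simulations with 25 members shifted by -0.3, the preset correlation found the list in 10 of 10 simulations and called 0 of 320 unshifted lists, and the estimated correlation found it in 6 of 10. The simulated lists were random genes, with noise drawn independently for each probe set. They cannot show whether the preset correlation avoids false calls for lists whose members vary together. Members were also tested with adjustment over the list alone. Chromosomes were tested with camera in the same way, and windows of 60 neighbouring genes were described without a test.

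Because the clones share the parent arrays, probe sets passing in both were set beside the number that independent lists give and beside 100 simulations of unchanged clones against the same parent arrays. Splitting the parent arrays between the comparisons would leave 1 array in each part and was not done.

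Alternatives were a filter on dim probe sets, quantile normalization, arrays centred on their medians or on ribosomal protein genes, an intensity trend with a robust prior, a fold-change minimum, an adjusted p under 0.01, averaging the probe sets of a gene, the replicate block, leaving out each array in turn, fits on 4 arrays, and fits with the 4 knock-in arrays as 1 group. The fits without 1 array had no replicate block, so the group left with 1 array held only 1 replicate number. Pseudocounts were not varied since the values are on a log scale. Figures were drawn with matplotlib 3.10.9.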

Results

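Gene expression was measured on 6 arrays of HCT116 colorectal carcinoma cells: 2 of the wild-type parent and 2 of each of 2 knock-in clones that carry IDH1 R132H on 1 allele. The mutant enzyme makes D-2-hydroxyglutarate, which competes with oxoglutarate at the TET DNA demethylases and other dioxygenases. The series asks whether the mutation alters DNA methylation and silences genes. Median signals of the arrays lay between 6.66 and 6.72 on the log2 scale.

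The arrays also differed by the replicate number of the labels. Signal of the 18S ribosomal RNA control (5' probe set) was higher in replicate 1 than in replicate 2 of each group: 11.89 against 9.77 in the parent, 11.43 against 8.69 in clone 1 and 12.21 against 8.60 in clone 2. The difference between the 3' and 5' control probe sets of ACTB was 1.44 and 1.32 in the parent, 0.84 and 1.30 in clone 1, and 0.80 and 1.34 in clone 2, with replicate 1 first. That of GAPDH lay between -0.04 and 0.04. Some hybridization controls separated the parent from the clones: bioB was 8.37 and 8.38 in the parent and 8.58 to 8.72 in the clones, bioC 9.75 and 9.81 against 9.94 to 10.07, and cre 13.49 and 13.51 against 13.59 to 13.67, whereas bioD overlapped.

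**Figure D1:**
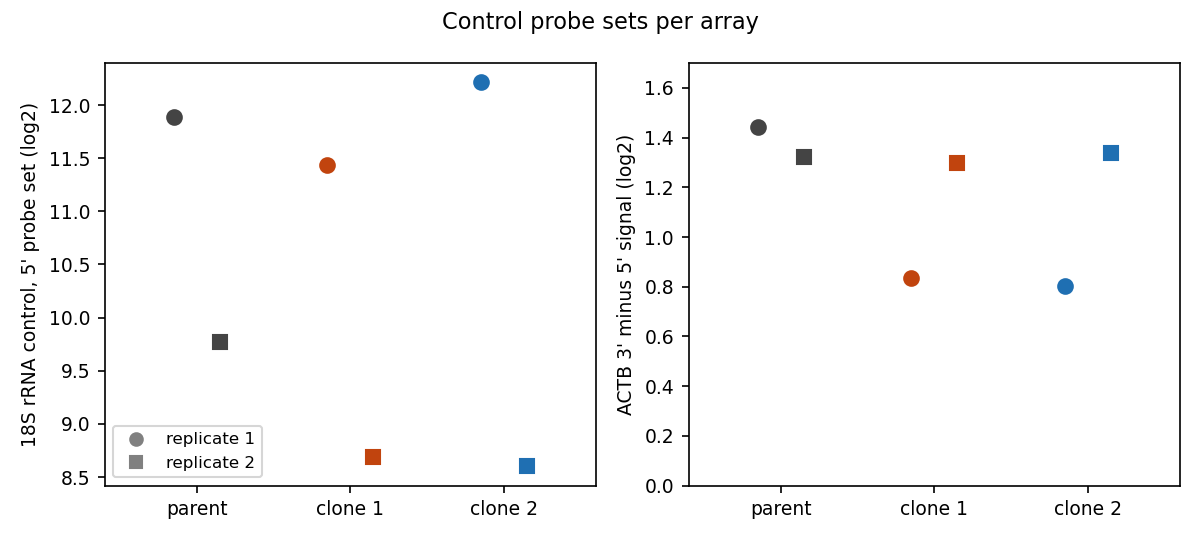
Log2 signal of the 18S ribosomal RNA control (left panel) and difference between the 3' and 5' log2 signals of ACTB (right panel), with 1 point per array, circles for replicate 1 and squares for replicate 2. The 18S control is higher in replicate 1 of every group, with 12.21 against 8.60 in clone 2.

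The transcripts of the edited gene and of its mitochondrial relative did not change detectably. IDH1 differed between both clones and the parent by -0.12 ± 0.07 (SE, n = 2 arrays per group; limma adjusted p = 0.790), and IDH2 by 0.07 ± 0.06 (adjusted p = 0.895). A further IDH2 probe set went the other way (-0.11, adjusted p = 0.852). The arrays do not separate the wild-type and mutant alleles of IDH1.

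Relative to the parent, both clones lost nearly all signal for UBB, a gene of polyubiquitin, the precursor of the protein tag for degradation. The epidermal growth factor receptor ligand EREG, the gap junction protein GJA1, the serpin family members SERPINB5 and SERPINA5, and the intermediate filament VIM also fell. So did the aldo-keto reductase AKR1C3, the growth factor homologue FGF13, the opsin OPN3, the collagen chain COL6A3, the bile acid binding protein FABP6 and the transcription factor SOX4. These calls concern the mean of both clones. Taken alone, AKR1C3 and SERPINA5 did not pass in clone 2 (adjusted p = 0.0899 for each) and SOX4 did not in clone 1 (adjusted p = 0.0510). With the block they did. The water and glycerol channel AQP3 was the only gene with a symbol that rose in the unblocked fit.

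UBB fell by 7.71 on the log2 scale (SE 0.10, 209-fold, adjusted p = 5.47e-06), from 11.70 and 11.85 in the parent arrays to between 3.89 and 4.25 in the knock-in arrays. The fall was -7.63 among replicates 1 and -7.78 among replicates 2. UBB lies on chromosome 17, and the array has no other probe set with this symbol alone. EREG changed by -3.16 ± 0.12 (adjusted p = 0.00195) and GJA1 by -3.00 ± 0.15 (adjusted p = 0.00812). SERPINB5 changed by -1.81 (adjusted p = 0.0166), VIM by -1.79 (adjusted p = 0.0367), AKR1C3 by -1.41 (adjusted p = 0.0239) and FGF13 by -1.38 (adjusted p = 0.0239). In the clones UBB and FGF13, and in clone 1 AKR1C3 and EREG, lay below 4.95 on the log2 scale, a limit for dim signals, where background limits a fold change. The falls of SERPINA5 (-1.17), OPN3 (-1.09), COL6A3 (-1.04), FABP6 (-0.87) and SOX4 (-0.78) had adjusted p between 0.0239 and 0.0464. None of the 4 other SOX4 probe sets passed, though all were lower, and 3 of them passed with replicate number as a block (adjusted p 0.00796, 0.0445 and 0.0203). AQP3 rose by 1.45 ± 0.11 (adjusted p = 0.0239), and its 2 other probe sets rose as well (1.46 and 1.15).

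In all, 19 of 22215 probe sets passed, 4 higher and 15 lower, or 1 gene higher and 14 lower. The higher ones were the 3 AQP3 probe sets and 1 without a symbol. The lower genes outside the naming rule were PLAAT3, lower in clone 1 alone, and IGFBP7 through a dimmer probe set (-1.27, adjusted p = 0.0387), both picked after their values were seen. Without any 1 of the 6 arrays the count was 2 to 4, and UBB and EREG alone among the 13 named genes kept their call in all 6 of these fits. GJA1 kept it in 3 fits, AKR1C3 and SERPINB5 in 1 each, and the other 8 in none. With replicate number as a block 108 probe sets passed, 22 higher and 86 lower. The block added rises of IL13RA2 (1.01, adjusted p = 0.0333 against 0.126 without it), GLT8D2 (0.85, adjusted p = 0.0106), S100A2 (0.75, adjusted p = 0.0257) and TRIB1 (0.59, adjusted p = 0.0204), and falls of S100A14 (-1.99, adjusted p = 0.00556 against 0.0520), ZBED2 (-1.72, adjusted p = 0.0330), SYT1 (-1.58, adjusted p = 0.0190) and S100A10 (-1.31, adjusted p = 0.0415). Smaller rises that passed with the block were those of PDLIM5 (0.50), OGDHL (0.48), HLA-DMB (0.48), RFPL3 (0.48) and MRC2 (0.44). Of 8 other PDLIM5 probe sets 2 passed with the block, and the other MRC2 probe set did not. Of these genes, each by its brightest probe set, GLT8D2, S100A14, ZBED2 and SYT1 passed with the block in each clone. S100A2, TRIB1, MRC2, PDLIM5, OGDHL, HLA-DMB and RFPL3 did not pass in clone 2 (adjusted p 0.0682 to 0.238), nor did S100A10 (adjusted p = 0.183) and IL13RA2 (adjusted p = 0.0571) in clone 1, although a dimmer PDLIM5 probe set passed in each clone (adjusted p 0.00650 and 0.0220). None of these brightest probe sets passed with the block when the 4 knock-in arrays were fitted as 1 group, a fit chosen after the data were seen (adjusted p 0.107 to 0.627).

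When the 4 knock-in arrays were fitted as 1 group, so that the difference between clones counted as spread, 4 probe sets passed, 1 of them without a symbol. UBB (adjusted p = 7.29e-07), GJA1 (adjusted p = 0.0211) and FGF13 (adjusted p = 0.0211) kept the call, and EREG did not (adjusted p = 0.340). With only 2 clones, and no wild-type clone, a change common to both cannot be assigned to the mutation.

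**Figure D2:**
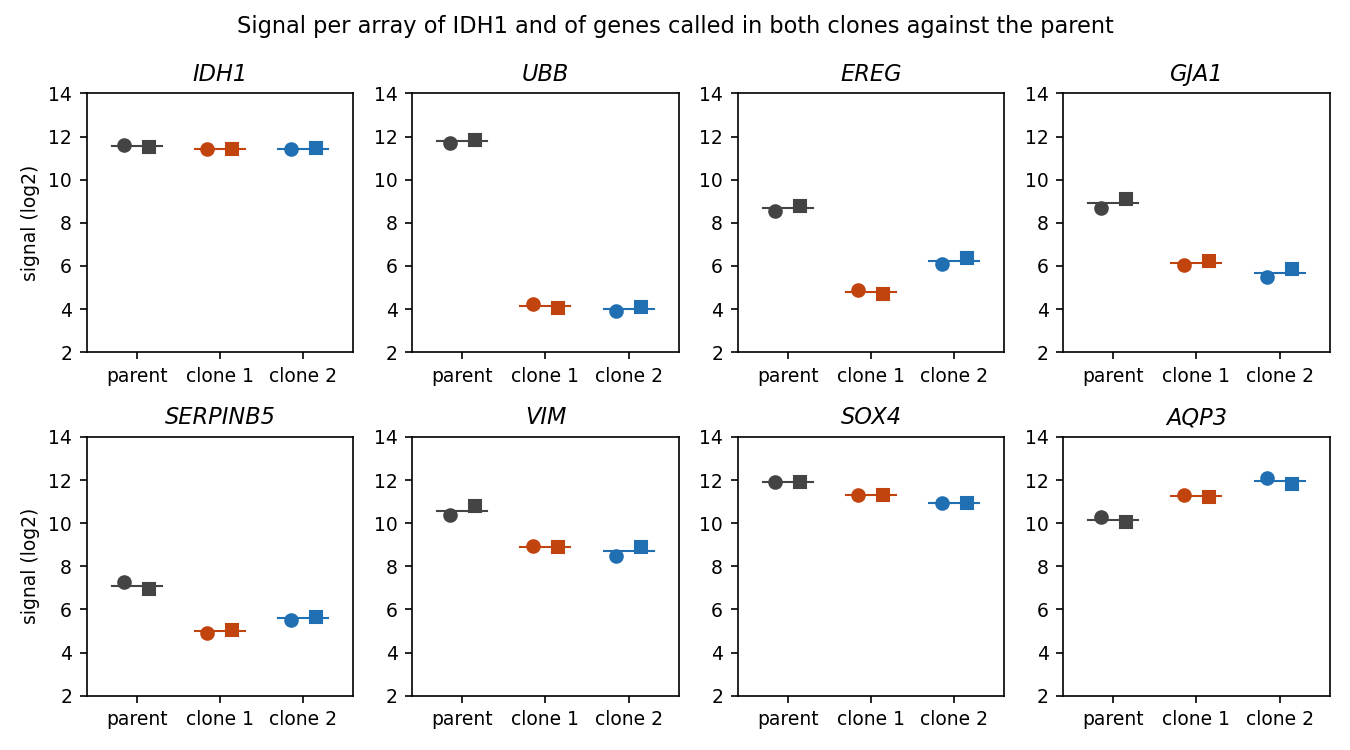
Log2 signal (vertical axis) of IDH1 and 7 genes that changed in the mean of both clones, with 1 point per array (circles for replicate 1, squares for replicate 2) and a line at each group's mean. UBB lies at 11.70 and 11.85 in the parent and between 3.89 and 4.25 in the clones.

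By camera with the preset correlation, genes of cholesterol and fatty acid synthesis, epithelial adhesion and growth-factor response and targets of the antioxidant factor NRF2 were shifted down in the mean of both clones, and genes of oxidative phosphorylation and KRAB-type zinc finger genes slightly up. None of these calls held with an estimated correlation. In all, 6 of 33 lists passed camera with the preset correlation, and 0 passed with an estimated correlation (2 at unadjusted p under 0.05) or by directional fry. Fry without regard to direction, which asks whether members changed in either direction, called 13. Leaving out 1 array gave 3 to 7 lists.

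Of 24 measured cholesterol and fatty acid synthesis genes none passed over all genes tested, and 7 were lower adjusted over the list alone (0 and 14 with the block), with MSMO1 (-0.43) and SREBF2 (-0.32) among those with the smallest p. Their median was -0.23 (adjusted p = 6.38e-10, and adjusted p = 0.803 with an estimated correlation). The shift came from clone 1: the median against the parent was -0.51 and -0.42 in clone 1 and -0.0087 and 0.12 in clone 2, with replicate 1 first. Of 32 epithelial adhesion genes, which include RAB25 (-0.66) and ITGB4 (-0.70), none passed, 1 was lower adjusted over the list alone (2 and 9 lower with the block) and the median was -0.10 (adjusted p = 1.02e-04, and adjusted p = 0.637 with an estimated correlation). ITGB4 (adjusted p = 0.0141) and RAB25 (adjusted p = 0.0197) passed with the block. This shift also came from clone 1, where the median was -0.26, while in clone 2 it was 0.04 (mean -0.03, camera direction down, adjusted p = 0.907). ITGB4 was an exception, with -0.53 in clone 1 and -0.87 in clone 2 (adjusted p 0.0216 and 0.00711 with the block).

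Of 29 immediate early and MAPK feedback genes 1 passed, EREG, and 1 was higher and 2 lower adjusted over the list alone. KLF6 (-0.55) and FOSB (0.42) did not pass. The list's median was -0.13 (adjusted p = 0.0219, and adjusted p = 0.943 with an estimated correlation). It did not pass without parent replicate 2 (adjusted p = 0.998, with the camera direction turned), clone 1 replicate 1 or clone 2 replicate 1. Of 26 NADPH and NRF2 genes AKR1C3 passed, and 3 were lower adjusted over the list alone, while ABCC2 (-0.48) did not pass over all genes (median -0.05, adjusted p = 0.0404, and adjusted p = 0.943 with an estimated correlation). Of 42 oxidative phosphorylation genes, such as UQCRB (0.16) and NDUFS1 (0.13), none passed in either count (median 0.05, adjusted p = 0.0404, and adjusted p = 0.943 with an estimated correlation). Of 55 KRAB-type zinc finger genes, such as ZNF211 (0.37) and ZNF235 (0.29), none passed in either count (median 0.07, adjusted p = 0.0364, and adjusted p = 0.637 with an estimated correlation). The zinc finger median was 0.10 in clone 1 and 0.0034 in clone 2. Each of these last 3 lists kept its call in 2 of the 6 fits without 1 array, with adjusted p up to 0.331, 0.353 and 0.111. The NADPH list kept it only without parent replicate 2 or clone 1 replicate 1, the oxidative phosphorylation list only without parent replicate 1 or clone 1 replicate 2, and the zinc finger list only without replicate 1 of either clone. With the block the NADPH (adjusted p = 0.0830) and oxidative phosphorylation (adjusted p = 0.0593) lists no longer passed. Adjusted over the list alone, 2 MAPK feedback genes were then higher and 3 lower, 4 NADPH genes lower and 1 zinc finger gene higher.

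Lists tied most directly to DNA methylation did not pass camera. The tests took in members whatever their signal in the parent. A gene already dim there can hardly fall further, so these results say little about silencing of such genes. Fry without regard to direction called the promoter methylation targets in both clones (adjusted p = 0.00369), clone 1 (adjusted p = 0.00856) and clone 2 (adjusted p = 0.00189), and the glioma methylator genes in clone 1 (adjusted p = 0.00173) and, with the block, in both clones (adjusted p = 0.0166). Between the clones it called both of these lists (adjusted p 0.0103 and 4.08e-04) and the DNA methylation machinery (adjusted p = 0.00205). With the block it called the machinery in clone 1 as well (adjusted p = 0.0132). Directional fry called none of the 3. Calls by fry without regard to direction were not particular to methylation. In both clones it also called the fibroblast and endothelial (adjusted p = 0.00263) and the neural and glial markers (adjusted p = 2.82e-05). It did not call the blood and immune (adjusted p = 0.276) or the liver and kidney markers (adjusted p = 0.711). The rest of this paragraph concerns the mean of both clones unless a clone is named. Among 42 genes known for promoter methylation in colorectal cancer VIM alone passed, and 2 were lower adjusted over the list alone. Their median was 0.02, their mean -0.05 and the camera direction down (adjusted p = 0.726). IGFBP7, a member, missed the threshold with its brightest probe set (-0.49, adjusted p = 0.212). Of 21 genes silenced in gliomas with the CpG island methylator phenotype none passed in either count, including CASP8 (-0.35) and MGMT (-0.23). Their median was -0.0076, their mean -0.07 and the camera direction down (adjusted p = 0.159, unadjusted p = 0.0385). Of 19 genes of the DNA methylation machinery, such as TDG (-0.23) and DNMT1 (0.06), none passed in either count (median 0.00054, mean -0.0079, camera direction down, adjusted p = 0.744). The cytidine deaminase APOBEC3B, a member, was lower in clone 2 than in clone 1 (-0.63, adjusted p = 0.0338), and higher in clone 1 than in the parent (0.43, adjusted p = 0.129, and adjusted p = 0.0495 with the block). With the block HELLS was also lower (-1.38, adjusted p = 0.0447) and MBD2 higher (0.54, adjusted p = 0.0227) in clone 2 than in clone 1. Of 28 genes of the IDH and TCA cycle list 1, lower, passed adjusted over the list alone and none over all genes (ME1 -0.36 and SDHA 0.21; median -0.02, adjusted p = 0.744). HIF and hypoxia targets (29 genes, median -0.05, adjusted p = 0.578) and ribosomal protein genes (51 genes, median -0.0030, adjusted p = 0.839) did not pass either.

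**Figure D3:**
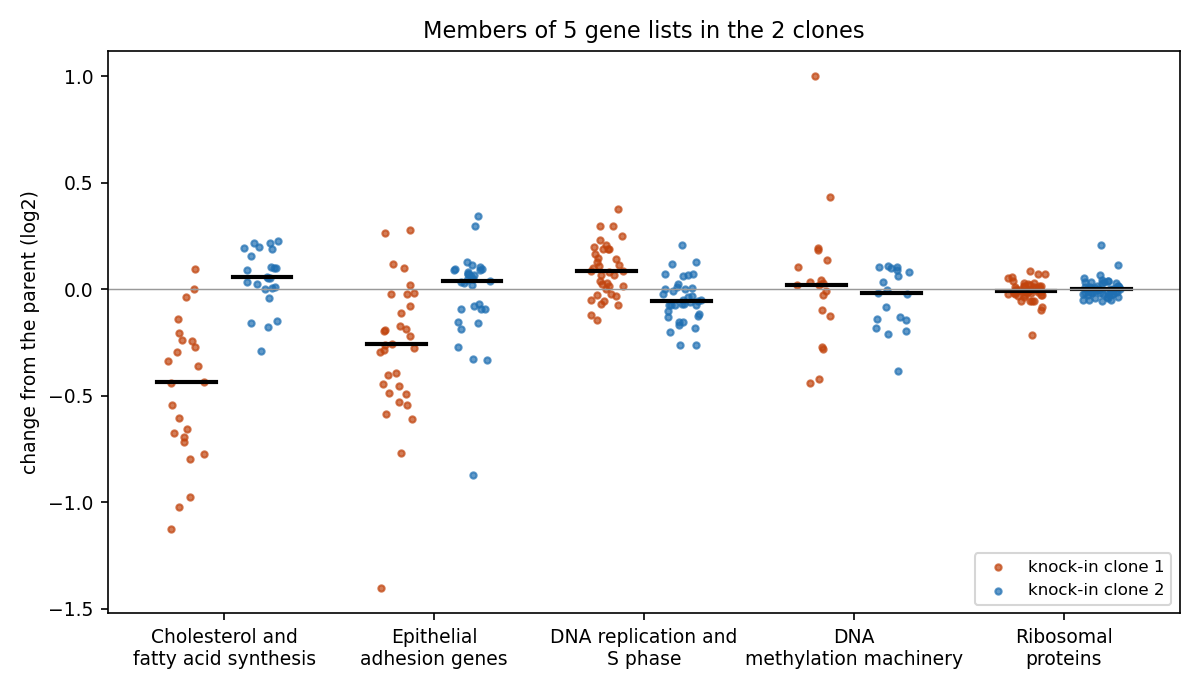
Change from the parent (log2, vertical axis) of each measured member of 5 gene lists in clone 1 and clone 2, with 1 point per gene and a black line at each median. Cholesterol and fatty acid synthesis genes have a median of -0.44 in clone 1 and 0.06 in clone 2.

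Taken alone, clone 1 lost signal for EREG, GJA1, SERPINB5, the phospholipase PLAAT3 and the calcium-binding protein S100A14 beside UBB. The stress-induced kinase PLK2, the phosphoinositide phosphatase INPP4B, AQP3, S100A2, the pseudokinase TRIB1 and the actin regulator MTSS1 rose. EREG and PLAAT3 lay below 4.95 in clone 1. PLAAT3 changed by -3.43 ± 0.13 (adjusted p = 0.00133), EREG by -3.88 (adjusted p = 0.00133), S100A14 by -2.66 ± 0.23 (adjusted p = 0.0247), GJA1 by -2.74 (adjusted p = 0.0102), SERPINB5 by -2.11 (adjusted p = 0.0102) and UBB by -7.62 (adjusted p = 1.39e-05). PLK2 rose by 1.54 ± 0.17 (adjusted p = 0.0427) and INPP4B by 1.45 ± 0.13 (adjusted p = 0.0318). AQP3 (1.12), S100A2 (1.10), TRIB1 (0.95) and MTSS1 (0.94) rose with adjusted p of 0.0475, 0.0242, 0.0237 and 0.0487, and the 3 other MTSS1 probe sets did not pass. THBS1 (1.38, adjusted p = 0.0396), TNFSF4 (1.33, adjusted p = 0.0128), NRG1 (1.32, adjusted p = 0.0255) and CSTA (-2.19, adjusted p = 0.0364) passed only with the block. Of the 4 other THBS1 probe sets 2 passed with the block, and of the 5 other NRG1 probe sets none. Altogether 70 probe sets passed, 13 higher and 57 lower, in 60 genes. With the block 422 passed, 137 higher and 285 lower, and without any 1 of the 6 arrays 2 to 12. UBB and EREG kept their call in all 6 of those fits, and PLAAT3 in 5, while AQP3, INPP4B, MTSS1, PLK2, S100A2 and TRIB1 kept it in none.

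In clone 1 sterol and epithelial adhesion genes had the lowest p of the lists by camera with the preset correlation. With an estimated correlation neither passed, and sterol genes (p = 0.0342) ranked behind epithelial adhesion (p = 0.0155) and zinc finger genes (p = 0.0240). Of the 24 cholesterol and fatty acid synthesis genes 2 were lower over all genes tested, MSMO1 (-0.97, adjusted p = 0.0331) and DHCR7 (-0.72, adjusted p = 0.0487), and 15 were lower adjusted over the list alone. With the block these counts were 12 and 20. HMGCS1 (-1.02, adjusted p = 0.0561) and IDI1 (-0.69, adjusted p = 0.0620) narrowly missed and passed with the block (adjusted p 0.0194 and 0.0203). The list's median was -0.44 (adjusted p = 1.78e-18, and adjusted p = 0.376 with an estimated correlation). Of the 32 epithelial adhesion genes RAB25 was lower (-1.40, adjusted p = 0.0487), 1 was higher and 15 lower adjusted over the list alone (with the block 5 were lower over all genes, and 1 higher and 16 lower over the list alone), and EPCAM (-0.40) and CLDN7 (-0.77) did not pass over all genes, although CLDN7 did with the block (adjusted p = 0.0161; median -0.26, adjusted p = 4.41e-09, and adjusted p = 0.376 with an estimated correlation). Both lists kept their call without any 1 of the 6 arrays.

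A further 4 lists passed in clone 1. Of the 29 MAPK feedback genes EREG, SPRY2 (-1.15, adjusted p = 0.0237) and KLF6 (-0.94, adjusted p = 0.0358) were lower, and 1 was higher and 3 lower adjusted over the list alone (median -0.19, adjusted p = 5.41e-04, and adjusted p = 0.850 with an estimated correlation). This list did not pass without parent replicate 2 (adjusted p = 0.293). Among the 26 NADPH and NRF2 genes AKR1C3 (-1.89, adjusted p = 0.0102) and ABCC2 (-0.96, adjusted p = 0.0334) were lower, and 4 were lower adjusted over the list alone (median -0.02, adjusted p = 0.0411, and adjusted p = 0.850 with an estimated correlation). It did not pass with the block (adjusted p = 0.113) or without parent replicate 1 or clone 1 replicate 2. Of 37 DNA replication and S phase genes, such as CDC6 (0.38) and CCNE1 (0.30), none passed in either count (median 0.08, adjusted p = 0.0204, and adjusted p = 0.850 with an estimated correlation), and the list did not pass without parent replicate 2 or clone 1 replicate 1 (highest adjusted p = 0.283). Of the 55 KRAB-type zinc finger genes, including ZNF14 (0.43) and ZNF211 (0.45), 3 were higher adjusted over the list alone and none over all genes, although both of these did pass with the block (adjusted p 0.0384 and 0.0343; median 0.10, adjusted p = 0.00517, and adjusted p = 0.376 with an estimated correlation). With the block 1 MAPK feedback gene was higher and 3 lower over all genes and 2 higher and 9 lower over the list alone, 5 NADPH genes were lower over all genes and 3 higher and 7 lower over the list alone, 1 DNA replication gene was higher over the list alone, and 2 zinc finger genes were higher over all genes and 6 over the list alone. Leaving out 1 array gave 5 to 7 lists.

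In clone 2 ARHGDIB, AQP3, the acyl-CoA synthetase ACSL5, the keratin KRT23 and the MAPK feedback inhibitor SPRY2 rose. Beside UBB, GJA1 and EREG, the cytokine TNFSF4, the cyclic AMP phosphodiesterase PDE4B and the growth factor NRG1 fell. ARHGDIB rose by 2.36 ± 0.13 (adjusted p = 0.0107), AQP3 by 1.79 (adjusted p = 0.0146), ACSL5 by 1.62 ± 0.11 (adjusted p = 0.0146), KRT23 by 1.26 (adjusted p = 0.0146) and SPRY2 by 1.09 (adjusted p = 0.0181). TNFSF4 changed by -3.22 ± 0.19 (adjusted p = 0.0108), PDE4B by -2.85 ± 0.19 (adjusted p = 0.0146), NRG1 by -2.20 (adjusted p = 0.0181), GJA1 by -3.25 (adjusted p = 0.0107), EREG by -2.44 (adjusted p = 0.0107) and UBB by -7.79 (adjusted p = 1.22e-05). PDE4B, TNFSF4 and SNAP25 lay below 4.95 in clone 2, and KRT23 and IL13RA2 in the parent. The 5 other NRG1 and 2 other PDE4B probe sets did not pass. IL13RA2 (1.28, adjusted p = 0.0167) and MGP (1.24, adjusted p = 0.0420) passed only with the block. Among list members VIM (-1.90, adjusted p = 0.0330), S100A4 (-0.90, adjusted p = 0.0360), SOX4 (-0.96, adjusted p = 0.0146) and the neural marker SNAP25 (-1.50, adjusted p = 0.0300) were lower. Altogether 40 probe sets passed, 10 higher and 30 lower, in 31 genes. With the block 179 passed, 55 higher and 124 lower, and without any 1 of the 6 arrays 1 to 11. UBB alone kept its call in all 6 of those fits, and AQP3, ACSL5 and SPRY2 kept it in none.

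No list passed in clone 2: camera called 0 of 33 (lowest adjusted p = 0.140; 5 at unadjusted p under 0.05), as did camera with an estimated correlation (0 at unadjusted p under 0.05) and directional fry. Fry without regard to direction called 10, against 16 in clone 1. Without parent replicate 1, parent replicate 2 or clone 2 replicate 2, camera called 3, 3 and 2. Cholesterol and fatty acid synthesis genes had a median of 0.06 (adjusted p = 0.452), with SREBF2 (-0.29) and IDI1 (0.22) among those with the smallest p.

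Probe sets that changed in both clones were mostly lower in both. UBB, EREG, GJA1, SERPINB5, VIM, FGF13, OPN3, COL6A3 and FABP6 were among those lower in each clone against the parent, and AQP3 was higher in each. ARHGDIB, ACSL5 and SPRY2 changed in opposite directions. In number, 2 probe sets were higher in both clones, 10 lower in both and 3 opposite. Independent lists would share 0.0059 and 0.077, a figure that ignores the shared parent arrays. The 100 simulations with unchanged clones called no probe set in either clone, so they give no value to set against this overlap. The shared total of 12 became 41 with the block (6 higher, 35 lower and 14 opposite, against 0.339 and 1.59 from independent lists and at most 4 in a simulation, where at most 6 were called in a clone), and 1 to 3 without any 1 of the 6 arrays. With the block the shared falls took in RETREG1, FANCF, SATB1 and TNFAIP3, picked after their values were seen, of which FANCF and SATB1 lay below 4.95 in the clones. Fold changes of the clones correlated across probe sets with r = 0.386, against a mean of 0.499 in the simulations. Their covariance was 0.0139 against 0.00386, a difference of 0.01005. The simulated clones shared the parent arrays in the same way, so this difference already leaves out the shared parent noise that the simulations model. Parent noise beyond the spread between these arrays may still add to it, and the parent arrays could not be split. A covariance also gives most weight to large changes such as that of UBB (-7.62 in clone 1 and -7.79 in clone 2). It does not show how broadly changes were shared.

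**Figure D4:**
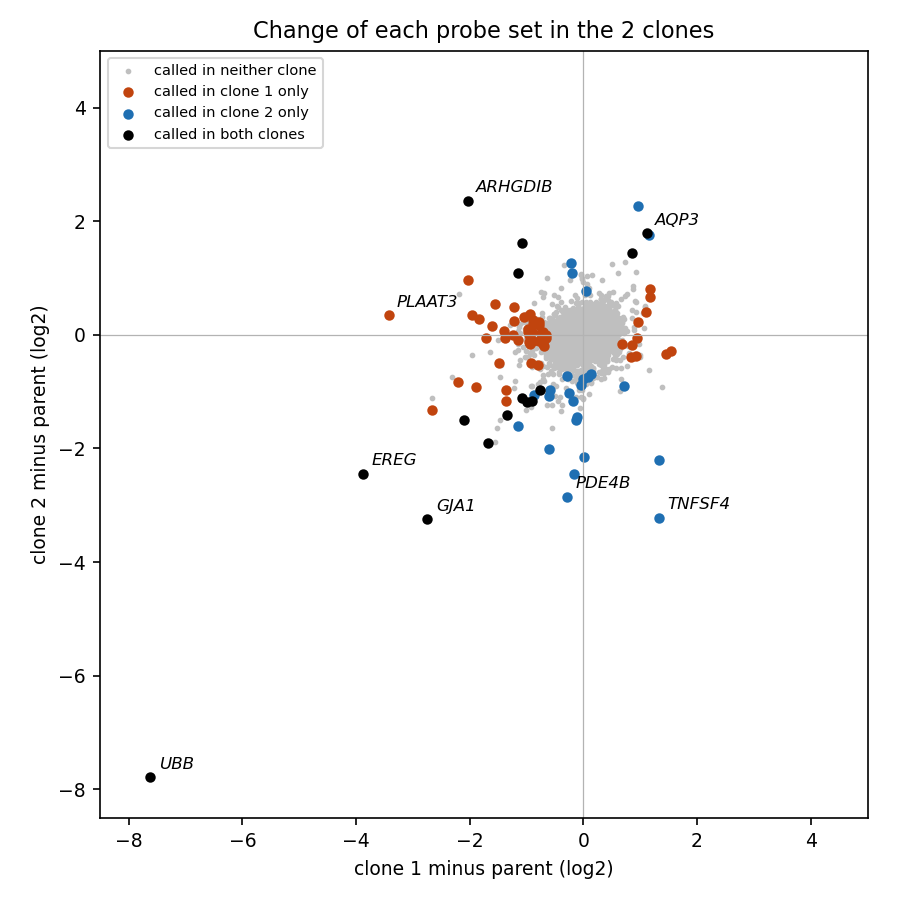
Log2 fold change against the parent in clone 1 (horizontal axis) and clone 2 (vertical axis), with 1 point per probe set, coloured by the clone or clones in which it passed the test. UBB lies at -7.62 and -7.79, while ARHGDIB was lower in clone 1 and higher in clone 2.

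More probe sets differed between the clones than between either clone and the parent. Clone 2 had more signal than clone 1 for ARHGDIB, PLAAT3, the annexin ANXA10, ACSL5, the growth factor binding protein FGFBP1 and SPRY2. It had less for TNFSF4, NRG1, PDE4B, the matrix protein THBS1, the lipid droplet protein PLIN2 and PLK2. The differences were 4.39 ± 0.13 for ARHGDIB (adjusted p = 0.00102), 3.78 for PLAAT3 (adjusted p = 0.00111), 3.01 for ANXA10, 2.71 for ACSL5 and 2.24 for SPRY2 (adjusted p = 0.00134 for all 3), and 2.31 ± 0.16 for FGFBP1 (adjusted p = 0.00834). In the other direction they were -4.54 ± 0.19 for TNFSF4 (adjusted p = 0.00134), -3.52 ± 0.18 for NRG1 (adjusted p = 0.00298), -2.57 for PDE4B (adjusted p = 0.00877), -2.31 for THBS1 (adjusted p = 0.0231), -2.17 for PLIN2 (adjusted p = 0.0115) and -1.83 for PLK2 (adjusted p = 0.0185). PLAAT3 in clone 1 and TNFSF4 and PDE4B in clone 2 lay below 4.95. Other probe sets of NRG1 (5), PDE4B (2), THBS1 (4) and PLIN2 (1) did not pass, although with the block 1 of PDE4B and 2 of THBS1 did. CSTA (2.91, adjusted p = 0.0105) passed only with the block. Altogether 193 probe sets passed, 114 higher and 79 lower in clone 2, in 148 genes. With the block 757 passed, 405 higher and 352 lower, and without any 1 of the 6 arrays 7 to 78. ARHGDIB, PLAAT3, ANXA10, ACSL5, SPRY2 and TNFSF4 kept their call in all 6 of those fits, NRG1 in 5 and THBS1 in none.

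Between the clones sterol and epithelial adhesion genes had the lowest p of the lists by camera with the preset correlation. Neither passed with an estimated correlation, and with the block DNA replication genes had the lowest p by that test (0.0308, against 0.0523 for sterol and 0.0665 for epithelial genes) and alone passed directional fry (adjusted p = 0.0424). Of the 24 cholesterol and fatty acid synthesis genes 8 were higher in clone 2 over all genes tested and 16 adjusted over the list alone (12 and 17 with the block), among them MSMO1 (1.08, adjusted p = 0.0146), IDI1 (0.91, adjusted p = 0.0210), DHCR7 (0.77, adjusted p = 0.0270) and HMGCS1 (1.12, adjusted p = 0.0292). The median was 0.56 (adjusted p = 1.84e-18, and adjusted p = 0.360 with an estimated correlation). Of the 32 epithelial adhesion genes RAB25 was higher (1.47, adjusted p = 0.0282), and 11 were higher and 1 lower adjusted over the list alone. With the block 9 were higher over all genes, EPCAM (0.47, adjusted p = 0.0268) among them, and 16 higher and 2 lower adjusted over the list alone (median 0.25, adjusted p = 3.89e-07, and adjusted p = 0.360 with an estimated correlation). MAPK feedback genes were higher in clone 2: SPRY2, EREG (1.43, adjusted p = 0.0197) and KLF6 (0.77, adjusted p = 0.0338) passed of 29, with 4 higher and 1 lower adjusted over the list alone (median 0.11, adjusted p = 0.00672, and adjusted p = 0.896 with an estimated correlation). With the block 4 were higher and 1 lower, and 6 higher and 1 lower adjusted over the list alone. This list did not pass without clone 1 replicate 1 or clone 2 replicate 2 (highest adjusted p = 0.568).

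Lists of lower expression in clone 2 than in clone 1 were those of DNA replication, G2/M, mesenchymal, Wnt and zinc finger genes. Of 37 DNA replication and S phase genes, such as MCM2 (-0.34) and TK1 (-0.45), none passed in either count, and TK1 passed with the block (adjusted p = 0.0291; median -0.15, adjusted p = 8.75e-05, and adjusted p = 0.618 with an estimated correlation). The same held for 36 G2/M genes, such as TOP2A (-0.38) and CDKN3 (-0.31), with a median of -0.11 (adjusted p = 0.0228, and adjusted p = 0.896 with an estimated correlation), a list that did not pass without clone 1 replicate 1 or clone 2 replicate 2. Of 31 mesenchymal genes S100A4 (-1.62, adjusted p = 0.00437), THBS1 and CCN2 (-0.82, adjusted p = 0.0292) were lower, and 1 was higher and 6 lower adjusted over the list alone (median -0.07, adjusted p = 0.0231, and adjusted p = 0.429 with an estimated correlation). It did not pass with the block (adjusted p = 0.0809) or without replicate 1 of either clone. Of 21 Wnt targets and stem cell genes BMP4 was lower (-1.14, adjusted p = 0.0219) and 5 were lower adjusted over the list alone, while TGFBR2 (-0.54) passed over all genes only with the block (adjusted p = 0.0211; median -0.07, adjusted p = 0.00672, and adjusted p = 0.360 with an estimated correlation). Of the 55 zinc finger genes, such as ZNF14 (-0.43) and ZNF85 (-0.29), none passed in either count, and ZNF14 passed with the block (adjusted p = 0.0270; median -0.03, adjusted p = 0.0277, and adjusted p = 0.360 with an estimated correlation), and the list did not pass without clone 1 replicate 2 or clone 2 replicate 1. With the block 1 DNA replication gene was lower over all genes and 4 over the list alone, 1 mesenchymal gene was higher and 4 lower over all genes and 3 higher and 8 lower over the list alone, 5 Wnt genes were lower over all genes and 1 higher and 6 lower over the list alone, and 2 zinc finger genes were lower over all genes and 3 over the list alone. Leaving out 1 array gave 6 to 8 lists. With the block camera also called HIF and hypoxia targets (median 0.10, adjusted p = 0.0296, and adjusted p = 0.881 with an estimated correlation), of which 2 were higher and 1 lower of 29, and 5 higher and 3 lower adjusted over the list alone.

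No chromosome passed as a whole, a question raised by clones grown from single cells. In GRCh38.p14 order, camera called 0 of 23 chromosomes in each comparison, with lowest adjusted p of 0.693 for both clones, 0.574 for clone 1, 0.488 for clone 2 and 0.983 between the clones. At unadjusted p under 0.05 the counts were 1, 2, 1 and 0. Chromosome medians lay between -0.03 and 0.05. Among 366 windows of 60 neighbouring genes, the highest median was 0.08, for SEPTIN4 to HELZ on chromosome 17 in clone 1, and the lowest -0.07, for ADH1A to ANXA5 on chromosome 4 in clone 1.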

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

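Tests chosen only after the result was seen were that of the ACTB control probe sets, that of genes switched off as the whole cause of the excess of lower probe sets and those of an offset of the knock-in arrays.

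A difference between the changes of the clones, tested as clone 2 minus clone 1 in limma, applied to 33 named genes and 8 lists. Of the genes, 17 were higher and 16 lower in clone 2. On the log2 scale the higher ones were ARHGDIB (4.39), PLAAT3 (3.78), ANXA10 (3.01), ACSL5 (2.71), FGFBP1 (2.31), SPRY2 (2.24), KRT23 (1.49), RAB25 (1.47), EREG (1.43), HMGCS1 (1.12), MSMO1 (1.08), AKR1C3 (0.98), ABCC2 (0.95), IDI1 (0.91), KLF6 (0.77), DHCR7 (0.77) and AKR1C2 (0.77). The lower ones were APOBEC3B (-0.63), S100A2 (-0.71), TRIB1 (-0.72), CCN2 (-0.82), MTSS1 (-1.001), BMP4 (-1.14), SNAP25 (-1.36), S100A10 (-1.42), S100A4 (-1.62), INPP4B (-1.79), PLK2 (-1.83), PLIN2 (-2.17), THBS1 (-2.31), PDE4B (-2.57), NRG1 (-3.52) and TNFSF4 (-4.54). Their adjusted p lay between 0.00102 and 0.0388. UBB was not among them. EREG, PLAAT3, AKR1C3 and KRT23 in clone 1, and TNFSF4, PDE4B and SNAP25 in clone 2, lay below 4.95 on the log2 scale, where background limits a difference.

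List medians of clone 2 minus clone 1 were 0.56 for cholesterol and fatty acid synthesis, 0.25 for epithelial adhesion and 0.11 for immediate early and MAPK feedback genes. They were -0.15 for DNA replication and S phase, -0.11 for G2/M, -0.067 for mesenchymal genes, -0.075 for Wnt targets and -0.034 for KRAB-type zinc finger genes. These calls came from camera with a preset correlation, and with an estimated correlation the adjusted p lay between 0.360 and 0.896.

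UBB signal fell to the dim end of the arrays in both clones. The 10 nearest measured genes on chromosome 17, from ZNF286A to MPRIP, had a median change of 0.074 in clone 1 and 0.13 in clone 2, which argues against a deletion that also takes these neighbours. The 301 probe sets with a similar signal in the parent had medians of -0.0031 and -0.00045. In the deposited values, then, no shift shared by such abundant transcripts accounts for the fall. The medians say nothing of the raw signals, since processing may already have levelled a shared scaling or labelling difference. A deletion limited to UBB, a sequence change under its probes and silencing of the gene stay open. The clones differed by -0.17 (adjusted p = 0.731), which decides nothing because both lay at the dim end. No wild-type clone is among the 6 arrays, so the genotype cannot be told apart from a change inherited from 1 ancestor cell.

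Sterol synthesis genes passed camera as lower in clone 1 and did not pass in clone 2, a call lost with an estimated correlation (adjusted p = 0.376), and 2 of 24 members passed over all genes, or 12 with the block. The median change of clone 1 was -0.42 in the weaker replicate number and -0.51 in the other, which argues against the difference between replicate numbers as the cause. The ACTB difference between 3' and 5' signal in clone 1 minus that in clone 2 was 0.034 in replicate 1 and -0.038 in replicate 2, which argues against 3' bias of the amplified RNA. A state of the clone 1 cultures, such as sterol supply or density, and a lasting difference of the clone both stay open: the medians of the replicate numbers differed by -0.10, but the labels do not say that these are separate cultures.

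More probe sets were lower than higher in both clones. Under the 3 other scalings the share of lower calls lay between 73.3% and 83.3%, but they moved the median change of all probe sets only to values between -0.0011 and 0.015, so they decide nothing about array scaling. Without the block, an offset of 0.13 added to the knock-in arrays was needed to bring the lower calls to 60% or less. The 51 ribosomal protein genes had a median change of -0.0030 (SD 0.039), which argues against such an offset of the deposited values as the cause in that fit. An offset that processing had already levelled for these genes could not be seen in them. With the block 0.05 was enough, within 2 SD of those genes, so by that limit an offset stays open there. The SD is a spread between genes and not the error of their median, and the median change of all probe sets was 0.012. Also with the block, 9 of 86 lower probe sets (10.5%) dropped in the clones below 4.95 on the log2 scale, a limit for dim signals, and 1 of 22 higher ones (4.55%) rose past it (2-sided Fisher's exact test, p = 0.683). Genes switched off in the clones thus stay open as a part of the excess, since 22 higher probe sets are too few to tell the shares apart. Among the other probe sets, 77 lower and 21 higher, 78.6% were lower, against 79.6% of all 108. Drops past this limit alone thus did not make up the excess. The limit was applied to the clones together, so genes switched off in only 1 clone could remain among the other probe sets. EREG, for example, had a mean of 4.79 in clone 1 and 6.22 in clone 2. The share therefore cannot decide whether genes switched off in the clones were the whole cause. The exact 95% binomial interval of that 78.6% (69.1% to 86.2%) and the Fisher test treat probe sets as independent. Probe sets of 1 gene and of the same arrays are not, so the interval does not measure the uncertainty of the share.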

How the results depend on the processing

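Tests chosen only after the result was seen were the fit of the 4 knock-in arrays as 1 group with the replicate block and the chromosome test with that block. The counts for both clones, clone 1 vs parent, clone 2 vs parent and clone 2 vs clone 1 rose with the replicate block to 108, 422, 179 and 757, with 41 probe sets shared. That fit removes the spread between replicate numbers by construction. In simulated data for both clones, drawn from that same fit, 7.81% of its calls were false. Without 1 array the counts ran from 2 to 4, 2 to 12, 1 to 11 and 7 to 78, the shared count from 1 to 3, and the lists from 3 to 7 for both clones and from 0 to 3 for clone 2. The lone array left in a group was then assumed to vary like the other groups, and fewer arrays leave fewer degrees of freedom. These fits had no replicate block, so that group held only 1 replicate number. Its fold changes then took in the difference between the numbers, which held 37.3% of the sum of squares. An adjusted p under 0.01 left 3, 3, 1 and 25, with 1 shared. Requiring an absolute log2 fold change of at least 1 left 36 for clone 1 and 73 between the clones. The filter on dim probe sets left 8 for both clones, 42 for clone 1 and 6 shared, although fewer probe sets were tested. An intensity trend with a robust prior gave 111 for clone 1, and averaging the probe sets of a gene gave 26 for clone 2 and 3 lists for both clones. For these 3 settings the cause was not tested. Fits on 4 arrays gave 12 for clone 1, 2 for clone 2 and 78 between the clones, with fewer arrays. For both clones, the 4 knock-in arrays as 1 group gave 4, with the population as a random block 7 (consensus correlation -0.18), and with the replicate block 5. Probe sets passing in each clone with the same sign numbered 12. With the clones as 1 group their difference counts as spread by construction. In the unblocked fit camera with an estimated correlation and directional fry each gave 0 lists for both clones, 0 for clone 1 and 0 between the clones. With the block the estimated correlation again gave 0, and directional fry gave 1 between the clones (DNA replication and S phase, adjusted p = 0.0424). Fry without regard to direction, another kind of test, gave 13, 16, 10 and 16 lists for both clones, clone 1, clone 2 and between the clones, and 19, 27, 19 and 28 with the block. Simulated shifts were found less often with the estimated correlation, in 6 of 10 simulations and with the block in 0 of 10. The simulated members did not vary together, so these simulations do not show which correlation suits the real lists. Quantile normalization and centring on medians or ribosomal protein genes moved no count by over 1.5 times. The chromosome count stayed at 0 with the dim filter and the block.

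Reversals concerned IDH1, IDH2 and 1 list. IDH1, clone 2 minus clone 1, was -0.015 with quantile normalization and ran from -0.0025 to 0.031 without 1 array. IDH2 with its probe sets averaged was -0.022 for both clones, -0.0045 for clone 1, -0.040 for clone 2 and -0.035 between the clones, since its other probe set goes the other way, and between the clones it ran from -0.0099 to 0.037 without 1 array. No IDH1 or IDH2 value passed a test. Immediate early and MAPK feedback genes, both clones vs parent, had medians from -0.24 to -0.0074 without 1 array, and its camera direction turned without parent replicate 2, the cause of which was not tested.

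Of the named gene results 20 passed only with the block and the other 56 kept their side of the threshold. Most named gene calls against the parent were lost in at least 1 of the 6 fits without 1 array. Results that passed in neither fit, such as those of IDH1 and IDH2, also stay on their side of the threshold. A total of results that stayed would therefore not measure how many calls held. Under quantile normalization 74 stayed, under centring on medians 74 and on ribosomal protein genes 72. Of the 20 list results 16 kept their call with the block, 17 with the dim filter and 17 with averaging. Pseudocount alternatives were not run, since the values are on a log scale. Signal over background limits fold changes at the dim end: UBB lay at percentile 12.9 in clone 1 and 10.6 in clone 2, FGF13 at 7.66 and 6.86, AKR1C3 at 12.3, EREG at 22.4 and PLAAT3 at 23.97 in clone 1, and PDE4B at 14.5 and TNFSF4 at 23.3 in clone 2, while IL13RA2 lay at 10.97 and KRT23 at 24.2 in the parent.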
